A study of Mus musculus with 3 samples.

How the data were processed

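H3K36me3, a histone mark that lies over the bodies of transcribed genes, was profiled by CUT&Tag in epithelial cells of the fetal mouse pancreas. In CUT&Tag an antibody directs a transposase that cuts and tags the DNA beside the mark. Per the labels, cells of wild-type C57BL/6 embryos were marked by the epithelial surface protein EpCAM and purified by flow cytometry from embryos at day E11.5, day E13.5 and day E15.5. The labels give 1 library per stage, 3 libraries in all, and a mean depth of 20000000 reads per sample. One sentence of the design text gives the middle stage a slightly different day, and the sample labels were followed. No second library of a stage and no control library without the antibody was analysed here.

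The submitters' processing notes name Bowtie2 2.4.2 and the mouse build mm10. How the reads were filtered, counted and scaled, and which gene models were used, is not given in the sources used here. The authors deposited 3 files with 25493 rows each, a gene identifier per row and 3 columns of signal headed PR, GB and SE, per the file headers. The headers do not spell out these abbreviations, so the columns keep their deposited names and no place along the gene is assumed for PR and SE. Reading GB as the gene body is an inference from the window lengths described below, which no source states. Identifiers were present in 24318 rows. The other 1175 rows, 4.61% of the total, had none and stayed out of every comparison, and 2 rows had an empty SE value.

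The structure of the columns was worked out from the values. PR times 6000 and SE times 12000 were whole multiples of a single step in each library, 0.16188 at E11.5, 0.16743 at E13.5 and 0.16292 at E15.5. At a tolerance of 0.05 steps, 100.0% of values above 0 were whole. With a step chosen wrongly, about 7% were. The SE sum was never below the PR sum in the 25491 rows with both, so the SE window was taken to hold the PR window, and the other 6000 positions of SE were computed by subtraction. These values behave as mean coverage over a window, not as counts of reads, so the depth of each file is unknown and no interval for counting error is given.

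The length of each GB window was recovered as the number of positions at which all libraries above 0 gave whole multiples of their steps, with sums kept to 2 decimals. This gave a length for 20538 identified rows, with a median of 19892 positions. Rows at 0 in at least 2 libraries have no length, and short lengths are therefore selected for nonzero values. Of the 5120 lengths of at least 50000 positions, 27.9% equalled a gene length in the RefSeq table of GRCm38.p6, against 4.1% after shifts of the lengths. On simulated windows, 92.1% of 1352 lengths were recovered exactly, and 98.7% of those recovered at 50000 positions or more were that long. Earlier forms of the search gave several lengths per row and were replaced.

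The reference table held none of the deposited Ensembl identifiers (0 matched), so no gene is named. The gene lists fixed before the data were examined, 28 in number, could not be used for the same reason, nor could the genes to be named in every case. The naming rule was the 10 genes with the largest rise and the 10 with the largest fall per comparison, leaving out predicted and clone-named genes. Without names that exclusion could not be applied, and at most 2 identifiers per direction are printed, for E15.5 against E11.5.

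For each gene the log2 ratio of the later over the earlier stage was taken as log2(value + 0.001). A gene entered a comparison where the higher library reached a floor, the median over identified rows and libraries (0.00413 for GB and 0.00407 for PR, in deposited units). Genes at least 2-fold apart were counted as higher or lower. The design fixed before the data were examined had a pseudocount of 1, written for values near 1. With medians near 0.004 it compresses nearly every ratio to 0, and the smaller pseudocount was chosen after the values were seen. Counts under the fixed pseudocount stand beside the main ones in the report. The use of GB as main column, the recovered lengths, the set of long gene bodies (at least 50000 positions), the ratio of PR to GB and the groups by GB signal were also chosen after seeing the data.

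Values were compared as deposited, although no source states that the authors scaled the libraries to each other. With 1 library per stage there is no test, no p-value and no measure of spread between embryos. Intervals of 95% come from 2000 resamplings of genes for ratios and 1000 for levels. They describe the spread over genes within these libraries and do not cover differences between libraries of one stage. Correlations are across genes, which are not independent replicates.

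The caller was checked on simulated GB data for E13.5 against E11.5, with 200 of the genes raised and an assumed 100 steps per fragment. Of genes raised 4-fold, 90.0% were called over 20538 lengths and 100.0% over the 5120 long gene bodies. Of genes raised 8-fold, 99.0% and 100.0% were called. Of unchanged genes above the floor, 22.0% were called over all recovered lengths and 1.0% over long gene bodies. The floor there was the median, over genes with a recovered length, of mean GB at E11.5 and E13.5. Genes without a recovered length were not simulated. These shares depend on the assumed fragment weight. PR and the comparisons with E15.5 were not simulated. Alternatives covered the scaling between libraries, the pseudocount, the floor, the fold threshold and the length of the gene body. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.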

Results

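H3K36me3 CUT&Tag signal was measured over genes in EpCAM-sorted pancreatic epithelial cells of mouse embryos from day E11.5, day E13.5 and day E15.5, with 1 library per stage. The stages were compared to follow the mark over genes during organogenesis of the pancreas. Over the 24318 identified genes, mean signal in the GB column, read here as the gene body from its recovered window lengths, was 0.00631 at E11.5, 0.00588 at E13.5 and 0.00924 at E15.5, in deposited units. Mean PR signal, over a window of 6000 positions, was 0.00552, 0.00506 and 0.0118 in the same order. Median GB over the identified genes went the other way at E15.5, with 0.00432, 0.00421 and 0.00371. These genes include those with a GB window that is short or of unrecovered length. In bodies of at least 50000 positions alone, mean GB was 0.00478, 0.00470 and 0.00484 in stage order. Over all identified genes, GB was listed at 0 in 12.9% at E11.5, 14.8% at E13.5 and 20.3% at E15.5, and PR in 7.59%, 11.9% and 22.1%. The libraries have no replicates, so all differences below are sizes in these libraries and none was tested. Read depth per file is unknown. Without a control library or a usable list of silent genes, the background level is unknown too. How much of each value is the mark itself was therefore not measured.

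Within each library, signal over gene bodies was lower in longer genes. Mean GB in bodies of 6000 to 12000 positions was 0.00709 at E11.5, 0.00663 at E13.5 and 0.0106 at E15.5. In bodies of at least 200000 positions it was 0.00365, 0.00373 and 0.00343. In the 5120 genes with bodies of at least 50000 positions, called long gene bodies here, mean PR and mean GB were nearly equal at the earlier stages. The ratio of mean PR to mean GB was 1.02 at E11.5 (95% interval over genes 0.994 to 1.05) and 0.971 at E13.5 (0.945 to 0.998). At E15.5 it was 2.44 (2.36 to 2.52). With medians instead of means the ratio was 0.812, 0.791 and 1.86 in stage order, so median PR was below median GB at the earlier stages. Mean signal in the part of the SE window outside PR was 0.888, 0.895 and 0.957 of mean GB in stage order. Its median was lower at E15.5, at 0.00275, 0.00296 and 0.000652, and it was at 0 in 9.04%, 13.4% and 36.1% of long genes. In bodies of at least 200000 positions, mean PR was 0.00445, 0.00421 and 0.00880 in stage order, but median PR differed little, at 0.00313, 0.00301 and 0.00320. The ratio of PR to GB is taken within a library, and any single scale factor for that library cancels in it.

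**Figure D1:**
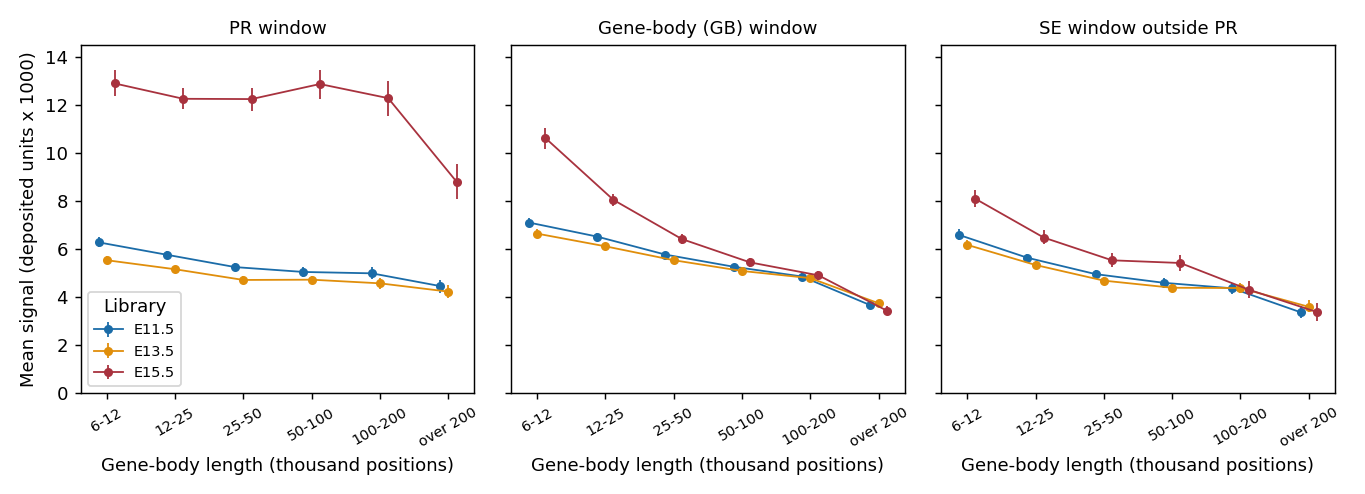
Mean signal (vertical axis, deposited units times 1000) by gene-body length class (horizontal axis, positions, in units of 1000) for the PR window, the GB window and the part of the SE window outside PR. Points are means over genes in 1 library per stage and bars are 95% intervals over genes. Mean PR is higher at E15.5 in every class, whereas mean GB at E15.5 is above the other libraries in bodies under 50000 positions and close to them in longer ones.

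E13.5 was set against E11.5 to describe the first interval. Signal over long gene bodies was nearly level, with a mean GB ratio of 0.982 (0.969 to 0.995), and mean PR was slightly lower at E13.5, with a ratio of 0.932 (0.898 to 0.969). Among long gene bodies above the floor, 91 of 3301 genes were at least 2-fold higher in GB at E13.5 and 86 were at least 2-fold lower. Over genes of all lengths the counts were 2810 higher and 3174 lower of 16346 for GB, and 4862 higher and 5542 lower of 16911 for PR. Under the pseudocount of 1 that was fixed beforehand, 0 genes were called in either direction. In simulated GB data for this pair, 22.0% of unchanged genes above the floor were called over all recovered lengths, under the assumed fragment weight. Over long gene bodies 1.0% were called, and PR was not simulated. The simulation had its own floor and left out genes without a recovered length, so 22.0% is not the noise rate of the counts above. Of those GB calls, 587 of the 2810 higher were at 0 at E11.5 and 760 of the 3174 lower at 0 at E13.5. Dividing each library by its median GB turned the mean GB ratio of long bodies to 1.04 and moved the median log2 GB ratio by 0.10.

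**Figure D2:**
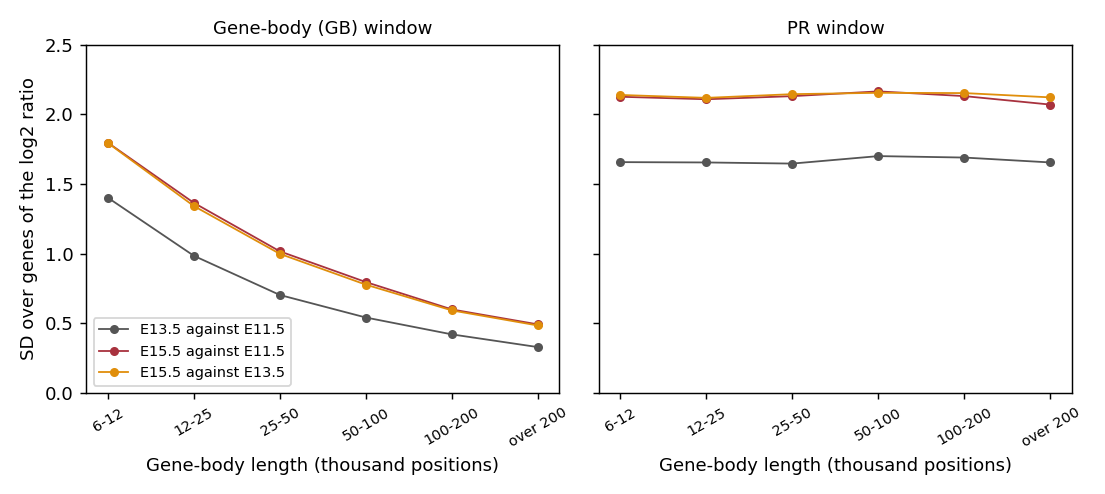
SD over genes of the log2 ratio between libraries (vertical axis) by gene-body length class (horizontal axis, positions, in units of 1000) for the GB and PR windows, 1 line per pair of libraries. For E13.5 against E11.5 the SD of GB goes from 1.40 in the shortest class shown to 0.328 in the longest, and that of PR is 1.66 and 1.65.

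E15.5 was set against E13.5 to describe the second interval. Mean PR of long genes at E15.5 was 2.59 times that at E13.5 (2.48 to 2.69). PR was higher in 59.7% of these genes and lower in 36.7%, with a median log2 ratio of 0.70. Mean GB was 1.03 times that at E13.5 (1.01 to 1.05). Most long genes went the other way, with GB higher in 42.3%, lower in 57.7% and a median log2 ratio of -0.11. PR was at least 2-fold higher in 9184 and lower in 4343 of 17609 genes of all lengths. How many unchanged genes would be called was simulated neither for PR nor for any comparison with E15.5, so noise may hold an unknown share of these calls. For PR that share may be large, since its Spearman correlation between these libraries was 0.130 across long genes. GB was at least 2-fold higher in 4415 and lower in 3541 of 16006 genes. Over long gene bodies the order was the other way, with 222 higher and 298 lower of 3227. The pseudocount of 1 left 8 genes higher and 0 lower for GB, and 0 in either direction for PR. Of the PR calls 67.9% were higher, whereas quantile normalization, which equalises the libraries by construction, gave 5945 higher and 5934 lower and moved the median log2 PR ratio by -1.12. Of the GB calls 55.5% were higher, against 44.9% after dividing by the median GB, which moved the median log2 ratio of GB by -0.34. Mean GB over long bodies became 0.840 times that at E13.5 under that scaling. Without a floor, 4744 genes were higher and 4917 lower in GB.

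E15.5 was set against E11.5 to describe the whole span. Mean PR of long genes at E15.5 was 2.41 times that at E11.5 (2.31 to 2.52), with PR higher in 59.0% of these genes, lower in 38.1% and a median log2 ratio of 0.60. Mean GB had a ratio of 1.01 (0.990 to 1.03), although 58.3% of long gene bodies had lower GB at E15.5. At least 2-fold differences in GB were found in 242 long genes higher and 286 lower of 3238, and over all lengths in 4258 higher and 3666 lower of 16048. In PR, 8862 genes were higher and 4605 lower of 17716. The pseudocount of 1 left 8 genes higher and 0 lower for GB. Of the PR calls 65.8% were higher, whereas quantile normalization gave 5962 higher and 5963 lower and moved the median log2 PR ratio by -0.997. Of the GB calls 53.7% were higher, against 46.5% after dividing by the median GB. That scaling moved the median log2 GB ratio by -0.23 and the mean ratio of long bodies to 0.877. PR of long genes stayed higher under it, at 2.10 times E11.5. Without a floor the GB counts were 4600 higher and 5029 lower.

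For E15.5 against E11.5, the 10 genes with the largest ratio above 1 in GB and the 10 with the largest below 1 were all listed at 0 in the other library and had either no recovered length or one under 6000 positions. A gene at 0 in 2 libraries gets no length by construction, so the length of such genes is unknown. ENSMUSG00000064441 was listed at GB 0, 0 and 1.58 in stage order, with PR at 0.0217, 0.0364 and 0.162. ENSMUSG00000098955 was listed at GB 0, 0 and 1.18, with PR at 0.0134, 0.0381 and 0.484. ENSMUSG00000099043 was listed at GB 0.608, 0 and 0, and ENSMUSG00000070136, with a recovered length of 79 positions, at 0.488, 0.114 and 0. The simulated windows held none that short, so the length of 79 positions is unchecked. No fold is given against a value of 0.

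Over the 3 stages, most genes followed none of the fixed profiles at the main floor. Of 18116 genes above the GB floor in at least 1 library, 1745 had a rising profile, 1508 a falling one, 1442 a peak at E13.5, 1554 a dip at E13.5 and 11867 none of these. Of 3601 long gene bodies, 114 had a rising profile, 128 a falling one, 30 a peak, 41 a dip and 3288 none. These are descriptions by size, with at least 2-fold over the whole for rising and falling. Peaks and dips rest on the E13.5 library in both steps.

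Genes at or above the GB floor numbered 12614 at E11.5, 12382 at E13.5 and 11481 at E15.5. In all 3 libraries 6193 genes reached it, where independent lists of these sizes would share 3032. In 6202 genes no library reached it. Of these, 1838 had GB at 0 in all 3 libraries, and such rows alone raise the overlap above that of independent lists.

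GB correlated more between libraries over long gene bodies than over all genes, and PR less. Spearman correlations of GB across these 5120 genes were 0.685 between E11.5 and E13.5, 0.600 between E13.5 and E15.5 and 0.600 between E11.5 and E15.5. Across all 24318 genes they were 0.433, 0.415 and 0.425, and across genes whose mean reached the floor 0.053, -0.0056 and -0.023. Choosing genes by their mean lowers a correlation between the libraries that make up that mean. For PR they were 0.124, 0.130 and 0.148 across long genes and 0.222, 0.230 and 0.239 across all genes. Of the 512 long genes with the highest GB in each library, E11.5 and E13.5 shared 236, E13.5 and E15.5 shared 251 and E11.5 and E15.5 shared 226, where independent lists would share 51.2. All 3 libraries shared 145, against 5.12. These top lists favoured shorter bodies in every library, with 10% of the long genes but 6.45, 6.58 and 6.94% of their length in stage order. Such a shared preference for length alone raises the overlap above that of independent lists.

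**Figure D3:**
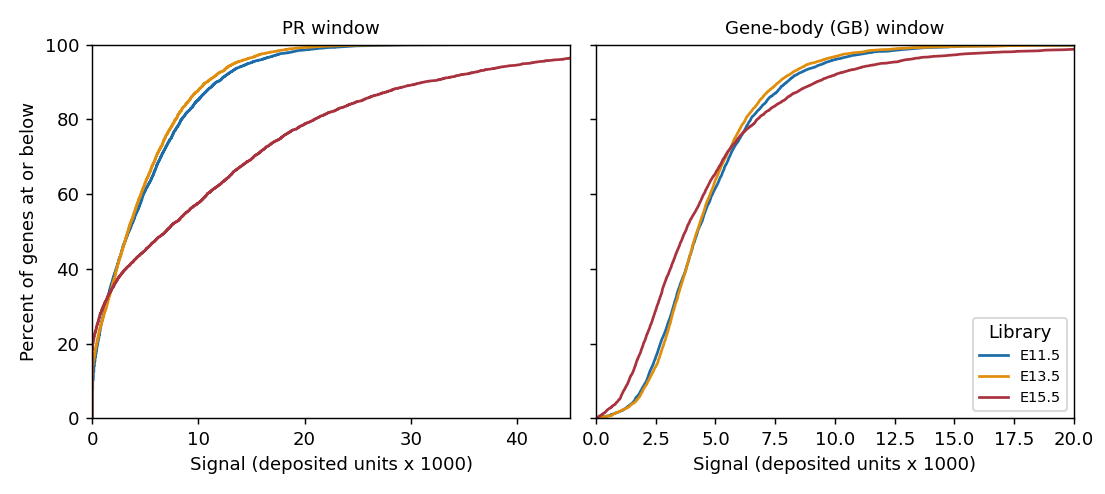
Cumulative percent of the 5120 long genes (vertical axis) at or below a signal (horizontal axis, deposited units times 1000) for PR and GB, 1 line per library; the horizontal axes end before the highest values. For PR the E15.5 line starts above the other lines, with 18.4% of genes at 0 against 7.48% at E11.5 and 12.0% at E13.5. It then crosses and lies to the right over most of the range. For GB the E15.5 line also starts above the others and crosses below them, with 58.3% of genes lower than at E11.5.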

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

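Of 227 recomputed values over 35 results, 107 stayed within 1.5 times the main value, or within its interval over genes for ratios. The pseudocount of 1 was fixed before the data were examined and became an alternative after they were seen. The alternatives with pseudocounts of 0.0001 and 0.005, with limits on gene-body length, without the top 5% of genes and with medians were chosen after seeing the data. The direction of PR in long genes at E15.5 against both earlier stages held under each alternative run for its mean ratio in those genes, from 2.10 to 2.44. Quantile normalization was run for the counts alone, where it evens out higher and lower PR calls by construction. The counts of 2-fold differences did not hold: they moved with the pseudocount and the floor, for GB also with the gene-body length and the fold threshold, and for PR with quantile normalization. Dividing by the median GB turned the balance of higher and lower GB calls. Depth is unknown, and 1 library per stage limits every comparison. No paired analysis was possible because each stage has 1 library and no test was run. Not run for lack of gene names were scaling by housekeeping genes, leaving out sex chromosomes and all alternatives for the gene lists. Identifiers were unique and the files hold no counts, peaks or scores, so merging rows of a gene, count scaling, overlap of regions and score filters were not run either. The cause of a change was not tested unless the alternative's construction gives it.

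Percentages here are of genes above the floor, in the order E13.5 against E11.5, E15.5 against E13.5 and E15.5 against E11.5. Main values for GB were 17.2, 27.6 and 26.5% higher and 19.4, 22.1 and 22.8% lower. For PR they were 28.8, 52.2 and 50.02% higher and 32.8, 24.7 and 26.0% lower. Main profiles were 9.63% rising, 8.32% falling, 7.96% peaking and 8.58% dipping. Larger pseudocounts shrink ratios by construction. With a pseudocount of 0.1, GB gave 0.281, 0.768 and 0.779% higher and 0.269, 0.300 and 0.336% lower. PR gave 0, 0.148 and 0.198% higher and 0% lower in all 3, and the profiles 0.0773, 0.0552, 0.232 and 0%. With the pseudocount of 1, GB gave 0, 0.050 and 0.0499% higher, and GB lower, PR and all 4 profiles gave 0%. With 0.005, GB gave 9.70% higher for the first pair and 11.1, 12.6 and 13.7% lower, PR 16.0% higher and 19.8% lower for the first pair, and the profiles 6.19, 4.28, 4.86 and 3.53%.

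With a floor 5 times higher, GB gave 35.7, 70.6 and 66.6% higher, and 43.8 and 14.2% lower for the first pairs. PR gave 87.4 and 83.0% higher at E15.5, and 49.2, 2.84 and 4.54% lower. Rising, falling, peaking and dipping profiles became 23.4, 5.32, 9.66 and 18.8%, so that most genes above that floor followed a profile. Genes reaching that floor numbered 760, 640 and 2334 in stage order, and 34 in all 3. With a floor 5 times lower they numbered 19506, 19489 and 17427, and 15218 in all 3. A 1.5-fold threshold gave 25.9% higher and 29.5% lower in GB for the first pair, 12.4% peaking and 14.4% dipping. Quantile normalization gave 33.6% higher in PR for E15.5 against E13.5. Bodies of at least 6000 positions gave 11.3% higher in GB for the first pair and 3.98% peaking. Bodies of at least 50000 positions gave 2.76, 6.88 and 7.47% higher and 2.61, 9.23 and 8.83% lower in GB, and profiles of 3.17, 3.55, 0.833 and 1.14%.

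Spearman correlations in the order E11.5 with E13.5, E13.5 with E15.5 and E11.5 with E15.5 were 0.053, -0.0056 and -0.023 for GB and 0.026, -0.098 and -0.153 for PR among genes whose mean reached the floor. Over all genes they were 0.433, 0.415 and 0.425 for GB and 0.222, 0.230 and 0.239 for PR. Over long gene bodies they were 0.685, 0.600 and 0.600 for GB and 0.124, 0.130 and 0.148 for PR.

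The ratio of mean PR to mean GB, 1.02, 0.971 and 2.44 in stage order, became 1.06, 1.05 and 2.70 over genes above 0 in every library, so that E13.5 went to the other side of 1. It was 0.895, 0.847 and 1.68 in bodies of 12000 to 50000 positions, 0.892, 0.844 and 2.09 without the top 5% of genes by PR, and 0.812, 0.791 and 1.86 with medians. After dividing each library by its median GB, the mean PR ratios of the pairs became 0.992, 2.11 and 2.10 and the mean GB ratios 1.04, 0.840 and 0.877. All 3 GB ratios crossed 1, and the main interval of E15.5 against E11.5 already held 1. Without the top 5% of genes in any library, PR was 2.44 and 2.29 for E15.5 against E13.5 and E11.5, and GB 0.936 and 0.923, both now below 1. In bodies of 12000 to 50000 positions PR gave 0.896, 2.48 and 2.22 and GB 0.947, 1.249 and 1.18.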

Other observations

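All tests in this part were chosen after the results were seen.

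Body signal of long genes was held by fewer genes at E15.5. The top 10% of long genes by GB held 23.4% of the summed body signal at E15.5, against 15.7% at E11.5 and 15.4% at E13.5. Grouped by GB signal at E13.5, long genes in the top group of 5 had a mean GB ratio of 1.17 for E15.5 against E11.5 (95% interval over genes 1.12 to 1.22). Those in the lowest group had 0.917 (0.870 to 0.968). PR and GB also went together more closely at E15.5, with a Spearman correlation across long genes of 0.444, against 0.297 and 0.263 at E11.5 and E13.5. Whether the PR window shares positions with GB is unknown, and shared positions would raise these correlations. Neither that nor a difference in the noise of PR between libraries was examined.

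PR signal was higher at E15.5 while mean signal over long gene bodies was level. One scale factor per library would move both columns alike, and the PR ratio divided by the GB ratio for E15.5 against E11.5 was 2.39, which argues against it. That value restates the pattern and is not a separate test of it. A few genes taking most of the PR signal is argued against too, since the PR ratio was 2.29 without the top 5% of genes in any library. The PR ratio was 2.19 (1.95 to 2.45) in the lowest of 5 groups by GB at E13.5 and 2.58 (2.37 to 2.79) in the highest. A rise limited to genes with gene-body signal stays open, since only 1 of the 5120 long genes had GB at 0 at E13.5. The stage itself, against the 1 library that stands for it, cannot be told apart, because libraries per stage number 1. A difference between stages and a difference in how this library was made both stay open.

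At least 2-fold differences in GB were rarer in longer gene bodies. For E13.5 against E11.5, the SD over genes of the log2 GB ratio was 1.40 in bodies of 6000 to 12000 positions and 0.328 in those of at least 200000. Sampling of few fragments in short windows predicts a log-log slope near -0.5, and the slope was -0.411, so such sampling is a candidate explanation for much of the difference. In the PR window, which has the same size in every gene, the SD was 1.66 and 1.65 in these classes and the slope 0.0036. Noise of that size in PR would also hide short genes that differ more between stages, so this stays open.

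Concentration of gene-body signal at E15.5 may come in part from thinner sampling of the E15.5 library. Such sampling would lower both its rank correlations and its shared top genes. The correlations with E15.5 were lower (0.600 against 0.685 between the earlier stages). The top-tenth lists were not, with a mean of 238.5 genes shared between E15.5 and an earlier library and 236 between the earlier ones. These values point different ways, and thinner sampling as a part of the pattern stays open. As the only source it is argued against, since random thinning would leave mean ratios alike across the groups by GB at E13.5. The mean GB ratio for E15.5 against E11.5 was 0.917 (0.870 to 0.968) in the lowest group and 1.17 (1.12 to 1.22) in the highest. No biological explanation was tested for this pattern.

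One row without an identifier had the highest GB of such rows in all 3 libraries, at 0.945 at E11.5, 0.860 at E13.5 and 3.99 at E15.5, with PR at 0.573, 0.532 and 2.60.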
